A study of Homo sapiens with 6 samples.

How the data were processed

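Total RNA of cultured MKN45, HER2R and CEAR cells was measured by RNA sequencing, with 2 libraries per line and 6 in all. Per the labels' protocols, cells grew in DMEM/F-12 with serum, RNA was isolated with RNeasy columns, and stranded total RNA libraries were made with Ribo-Zero Plus depletion of ribosomal RNA. GRCh38 and limma are named, per the submitters' processing notes, with no version and no role given. The aligner, the counting program and the gene annotation are not given in the sources used here. The values deposited by the authors are raw counts per gene symbol, and they were whole numbers in all 6 libraries. No column of the table went unmatched to a sample. Totals ran from 39657353 to 57964246 counts, and 1 count in a library is 0.0177 to 0.0255 CPM on the scaled totals used for levels. The ribosomal RNA precursor gene RNA45S5 held 8.88% to 10.7% of counts and 5 abundant noncoding RNAs together 11.5% to 14.7%. The libraries of a line were not copies of one another, since their counts differed with a chi-square per degree of freedom of 134 in MKN45, 64.2 in HER2R and 94.7 in CEAR, where repeated counting of 1 library would give about 1.

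Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr by group, which kept 14958 of 29744 symbols and removed 14786. Libraries were scaled by TMM factors, and 1 quasi-likelihood model with a term per line was fitted to all 6 libraries, with 3 residual and 3.51 prior degrees of freedom. The contrasts were HER2R against MKN45, CEAR against MKN45 and HER2R against CEAR. The p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and "edgeR adjusted p" means this value throughout. A gene was called at an adjusted p under 0.05. Log2 fold changes are the fitted ones, and their SE is the size of the log2 fold change over the square root of its F statistic. Levels in CPM use library totals of the tested genes scaled by the TMM factors. With 0 counts in a line, a fold was computed against a floor of 3 counts over its libraries and given as "at least". With 1 to 3 counts it is the ratio of the summed counts over the summed library totals, with a 95% interval from counting. Fitted values of such genes depend on the prior count and are no bounds.

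Before the data were examined, 38 gene lists, the named-gene rule, the tests and most alternatives were chosen. Of 989 distinct list symbols 906 matched directly, 46 by a GENCODE 29 name of the same gene, 9 by a RefSeq synonym, 1 was already in its list and 27 were not matched. GENCODE 29 gave positions to 22551 symbols. The list of mitochondrially encoded genes had no tested member, which left 37. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists, and repeated with an estimated correlation and with fry, a self-contained test. Lists can share members, so their results are not independent. A call lost with the estimated correlation does not show that correlation between genes made it. In HER2R against MKN45 a list with 1 tested member, which has no such correlation, went from camera adjusted p = 0.0421 to 0.577. The named genes were CEACAM5, ERBB2, IFNGR1, IFNGR2, JAK1, JAK2, IRF1, HLA-B, HLA-C, B2M and CD274 whatever their values, with others fixed by the same rule not reported here. To these came the 10 largest called changes per direction and comparison, among named protein or RNA genes at 5 CPM or more whose libraries did not overlap, and up to 4 called members per direction of each list described. Described were lists called by camera, lists with 1 in 4 or more of their members called, and the antigen, interferon, MHC, checkpoint, death receptor, adhesion and cell marker lists.

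The labels number the libraries of each line 1 and 2 without saying what the number means. Over all tested genes, which are not independent replicates, the difference of number 2 minus number 1 correlated between lines, at 0.378 for MKN45 and HER2R, 0.545 for MKN45 and CEAR and 0.355 for HER2R and CEAR, and the third principal component, with 17.9% of the variance, separated the numbers. A fit with the number as a term, called the replicate block, was therefore given beside results it changes. Alternatives fixed beforehand were the replicate block, RLE size factors, library size alone, no filter, a filter at 1 CPM, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood method, the libraries of the compared lines alone, a test against a fold of 1.5, and leaving out each library, where the line left with 1 library is assumed to vary like the others. Leaving out 5 abundant noncoding RNAs and thinning all libraries to equal totals were chosen after seeing the data.

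The methods were tested on simulated data, written after the real fits were first run, with 14958 genes for HER2R against MKN45 and 100 genes changed at each fold. edgeR called 27% of genes changed 2-fold and 91% of those changed 4-fold, and 4.84% of its calls were false. The replicate block called 28% and 92% with 7.63% false, limma-voom 26% and 89% with 5.69% false, and DESeq2 53% and 98% with 26.1% false. No number effect was simulated, so the block's values do not tell how it behaves on these libraries. A list of 30 genes raised 1.5-fold gave a camera p of 7.95e-22, and a list of 30 unchanged genes gave 0.95. Camera's error in correlated lists was not tested. Simulated covariance of fold changes was 0.344 with a shared effect and 0.0936 without. No separate MKN45-HER2 culture was analysed here.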

Results

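RNA was sequenced from 3 cultured lines of human gastric tumour cells. MKN45 is an established gastric cancer line that the labels call sensitive, and the others are described as its derivatives. HER2R is resistant to a bispecific antibody against HER2, the receptor encoded by ERBB2. CEAR is resistant to a bispecific antibody against CEACAM5, a glycoprotein of the epithelial cell surface. The source names in the labels are MKN45, MKN45-HER2 and MKN45-CEAR, and whether MKN45-HER2 is HER2R itself or a modified line it was raised from is not stated. Such T cell bispecific antibodies bind a surface antigen of the tumour cell with one arm and the T cell receptor complex with the other. Each line had 2 libraries. The labels list no treatment and do not say whether the resistant lines were kept under antibody or T cells before RNA was taken. The deposited values were raw counts per gene symbol, with library totals of 57964246 and 44219063 in MKN45, 39657353 and 40246614 in HER2R, and 39659202 and 43554345 in CEAR. Of 29744 symbols, 14958 passed the filter on low counts and were tested. Nothing in the labels says that the libraries of a line came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Levels are given in CPM, the usual read count scaled by library depth, as mean ± SD over the libraries of a line (n = 2).

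The first question was what became of the antigens. CEACAM5 (chromosome 19, 41708585 to 41729798 on GRCh38) was nearly lost in CEAR and kept in HER2R. It stood at 1724 ± 1014 CPM in MKN45, 1663 ± 886 CPM in HER2R and 9.10 ± 9.56 CPM in CEAR. The log2 fold change of CEAR against MKN45 was -7.56 (SE 1.08, edgeR adjusted p = 0.0156), and it stayed called when any 1 of the 6 libraries was left out. It moved to -6.79 without MKN45 library 2, -6.76 without CEAR library 1 and -9.52 without CEAR library 2. For HER2R against MKN45 it was -0.05 (SE 0.804, edgeR adjusted p = 0.974). ERBB2 (chromosome 17, 39687914 to 39730426) was present in all 3 lines, at 115 ± 15.7 CPM in MKN45, 83.5 ± 6.67 CPM in HER2R and 92.5 ± 23.9 CPM in CEAR. Its log2 fold change was -0.46 in HER2R (SE 0.206, edgeR adjusted p = 0.203) and -0.31 in CEAR (SE 0.205, edgeR adjusted p = 0.429), neither past the test. No separate MKN45-HER2 culture was analysed here, so these values compare HER2R with MKN45 alone. CEACAM6, a close relative of CEACAM5 on the same chromosome arm, fell in both derivatives, from 1063 ± 370.4 CPM to 22.9 ± 20.7 CPM in HER2R (-5.54, edgeR adjusted p = 0.0314) and 33.4 ± 35.0 CPM in CEAR (-4.99, edgeR adjusted p = 0.0487). Leaving out a library ended the call of CEACAM6 in HER2R (edgeR adjusted p = 0.0622 without MKN45 library 1, 0.0825 without MKN45 library 2, 0.155 without HER2R library 1, 0.105 without HER2R library 2), where the log2 fold change moved to -4.82 without HER2R library 1 and -7.01 without HER2R library 2. In CEAR it ended with any library but CEAR library 2 left out (edgeR adjusted p = 0.0862 without MKN45 library 1, 0.118 without MKN45 library 2, 0.0678 without HER2R library 1, 0.0674 without HER2R library 2, 0.0918 without CEAR library 1). The log2 fold change there moved to -4.19 without CEAR library 1 and -6.93 without CEAR library 2. Of 6 measured antigen and CEACAM family genes in HER2R, 0 rose, 1 fell and 5 did not pass the test. The HER2R antigen list gave 0 and 1 adjusted over the list alone, 1 and 2 with the replicate block, and camera adjusted p = 0.275. Of 6 such genes in CEAR, 0 rose, 2 fell and 4 did not pass the test. The CEAR antigen list gave 0 and 3 adjusted over the list alone, and camera adjusted p = 0.0252 (adjusted p = 0.962 with an estimated correlation). That call ended without MKN45 library 2, a fit that mixes line with number. CEACAM5 and CEACAM6, like HLA genes, MAGEA genes and histone genes, belong to families with near-identical copies, between which the counting could have split reads, so their levels are uncertain to that extent.

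**Figure D1:**
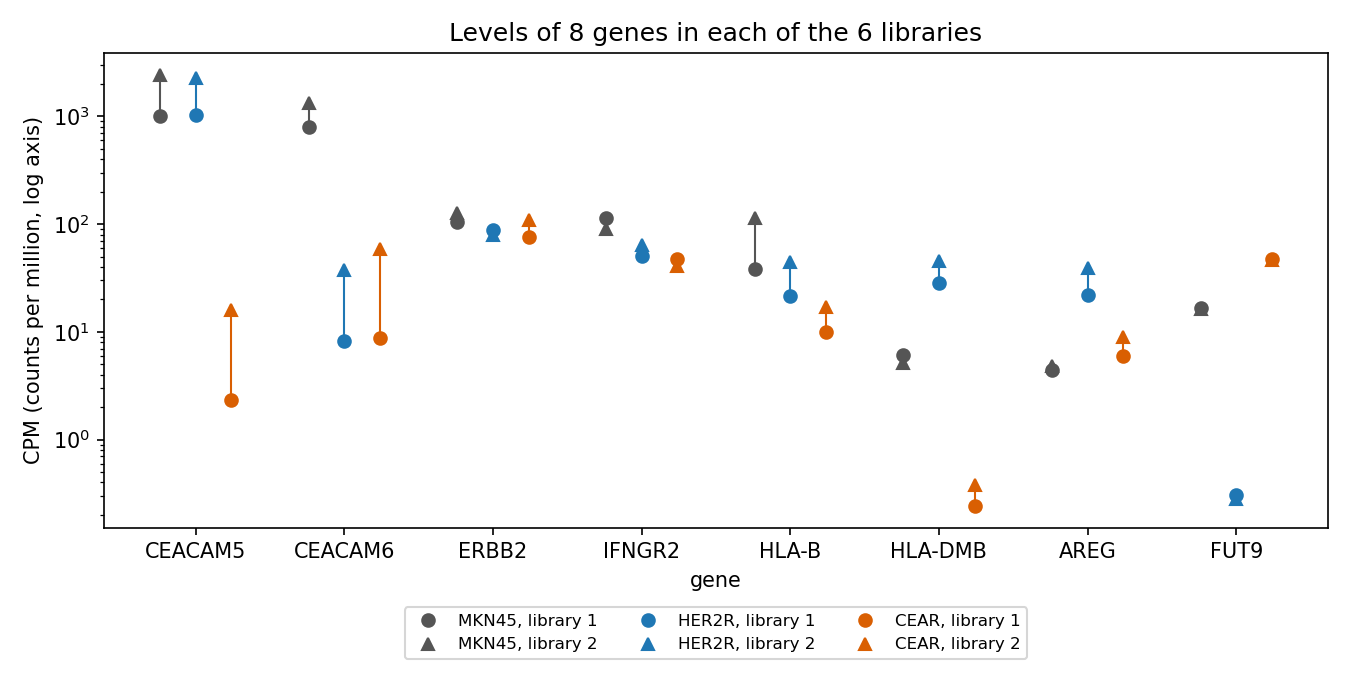
Level of 8 genes in each library, in CPM on a log axis. Circles are library 1, triangles library 2, and a line joins the libraries of a line of cells. CEACAM5 is at 1007 and 2441 CPM in MKN45, 1036 and 2289 CPM in HER2R, and 2.34 and 15.9 CPM in CEAR, while ERBB2 lies between 75.7 and 125.7 CPM in all 6 libraries.

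The comparison of HER2R with MKN45 asked what separates cells resistant to the HER2 bispecific from the sensitive line, and it cannot separate resistance from a modified source line or from culture. By camera at its preset correlation the hypoxia, mesenchymal, MAPK feedback, NF-kappaB and MHC class II lists were called higher and the MHC class I, NRF2 and cholesterol lists lower. None of these calls held with an estimated correlation (camera adjusted p = 0.541 to 0.794). That version called 0 lists in each comparison, so it does not tell the lists apart. In each list most members did not pass the test. EGLN3, an oxygen-sensing prolyl hydroxylase, rose from 3.97 ± 0.528 to 33.0 ± 5.79 CPM (log2 fold change 3.05, edgeR adjusted p = 0.00206). AREG, a ligand of the EGF receptor, rose from 4.59 ± 0.258 to 30.8 ± 12.3 CPM (2.75, edgeR adjusted p = 0.00892). ICAM1, an adhesion molecule bound by T cells, rose from 0.497 ± 0.124 to 12.5 ± 2.30 CPM (4.63, edgeR adjusted p = 0.00263). In all, 731 genes were higher and 726 lower in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 487 and 351 of them by over 2-fold.

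Among the largest rises were NOG, a secreted antagonist of bone morphogenetic proteins (28.7 ± 8.30 against 0.198 ± 0.105 CPM, log2 fold change 7.22, edgeR adjusted p = 0.00173), and COL12A1, a collagen (92.1 ± 59.3 against 0.841 ± 0.289 CPM, log2 fold change 6.74, edgeR adjusted p = 0.00372). So was ARSJ, an arylsulfatase (16.9 ± 0.843 against 0.153 ± 0.0410 CPM, log2 fold change 6.79, edgeR adjusted p = 0.00206). CD74, the invariant chain of MHC class II, had 2 counts over both MKN45 libraries and 13.9 ± 7.35 CPM in HER2R (695-fold, 95% counting interval 192 to 5750). CELF2, an RNA-binding splicing regulator, likewise had 2 counts in MKN45 (960-fold, 95% counting interval 265 to 7930), and DOC2B, a calcium sensor of vesicle release, had none, so it was at least 344-fold higher in HER2R. Such floors take 3 counts over the group, and floors and counting intervals cover counting error only. The largest losses included SLFN11, a factor that sensitises cells to DNA damage (0.459 ± 0.0357 against 50.03 ± 10.1 CPM, log2 fold change -6.76, edgeR adjusted p = 0.000779), and WNT16, a secreted WNT ligand (0.306 ± 0.000254 against 21.7 ± 2.94 CPM, log2 fold change -6.13, edgeR adjusted p = 0.000997). ALDH1A1, a retinaldehyde dehydrogenase, fell from 118 ± 58.5 CPM to 1 count over both HER2R libraries (8880-fold, 95% counting interval 1590 to 351000). SOSTDC1, an antagonist of bone morphogenetic protein and WNT signals, also fell to 1 count (1640-fold, 95% counting interval 294 to 64800), and GAP43, a growth-cone protein, to 0 counts, at least 1390-fold lower.

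Of 28 measured hypoxia and glycolysis genes, 7 rose, 0 fell and 21 did not pass the test. The hypoxia list gave 14 and 0 adjusted over the list alone, 17 and 0 with the replicate block, and camera adjusted p = 4.67e-09 (adjusted p = 0.577 with an estimated correlation). P4HA1, a collagen prolyl hydroxylase (1.37, edgeR adjusted p = 0.00813), KDM3A, a histone demethylase (1.11, edgeR adjusted p = 0.0134), and ADM, adrenomedullin (2.38, edgeR adjusted p = 0.0202), rose. Of 19 mesenchymal genes, 7 rose, 2 fell and 10 did not pass the test. The mesenchymal list gave 10 and 2 adjusted over the list alone, and camera adjusted p = 0.00038 (adjusted p = 0.541 with an estimated correlation). VIM, the intermediate filament vimentin, rose from 0.0898 ± 0.00169 to 6.12 ± 3.06 CPM (6.05, edgeR adjusted p = 0.00750). The transcription factors ZEB1 (4.02, edgeR adjusted p = 0.00868) and FOXC2 (2.21, edgeR adjusted p = 0.00237) rose too. The smooth-muscle actin ACTA2 (-1.79, edgeR adjusted p = 0.0239) and the matricellular protein CTGF (-3.47, edgeR adjusted p = 0.0267) fell. Of 26 feedback genes of the MAPK pathway, 4 rose, 1 fell and 21 did not pass the test. The MAPK list gave 11 and 2 adjusted over the list alone, 16 and 2 with the replicate block, and camera adjusted p = 0.00120 (adjusted p = 0.577 with an estimated correlation). JUN (1.42, edgeR adjusted p = 0.00428) and the phosphatase DUSP4 (1.25, edgeR adjusted p = 0.00815) rose, and the transcription factor ETV1 fell (-1.16, edgeR adjusted p = 0.0285). The call of the MAPK list ended without MKN45 library 2, a fit that mixes line with number. Of 10 ERBB receptors and ligands, 3 rose, 1 fell and 6 did not pass the test. The ERBB list gave 3 and 1 adjusted over the list alone, 4 and 2 with the replicate block, and camera adjusted p = 0.0914 (0.0458 with the replicate block, 0.577 with an estimated correlation, range over refits at the preset one 0.0223 to 0.449). The ligands AREG, EREG (1.47, edgeR adjusted p = 0.00662) and HBEGF (1.93, edgeR adjusted p = 0.00713) rose, and the receptor ERBB3 fell (-0.92, edgeR adjusted p = 0.0272). Of 21 NF-kappaB targets, 3 rose, 0 fell and 18 did not pass the test. The NF-kappaB list gave 6 and 0 adjusted over the list alone, 10 and 0 with the replicate block, and camera adjusted p = 0.00194 (adjusted p = 0.541 with an estimated correlation). Those that rose were ICAM1, NFKB2 (1.43, edgeR adjusted p = 0.00497) and the cytokine CSF1 (2.58, edgeR adjusted p = 0.0257).

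Of 24 MHC class I presentation genes, 1 rose, 3 fell and 20 did not pass the test. The class I list gave 1 and 3 adjusted over the list alone, 1 and 11 with the replicate block, and camera adjusted p = 0.0143 (adjusted p = 0.794 with an estimated correlation). The transactivator NLRC5 fell from 34.9 ± 1.37 to 10.1 ± 1.001 CPM (-1.79, edgeR adjusted p = 0.00922). The peptide-loading protein TAPBP (-1.14, edgeR adjusted p = 0.00605) and the peptide transporter TAP1 (-0.83, edgeR adjusted p = 0.0323) fell, and the peptide trimmer ERAP2 rose (0.81, edgeR adjusted p = 0.0255). The list's call ended without HER2R library 1 or MKN45 library 2, fits that mix line with number. HLA-B (-1.22, edgeR adjusted p = 0.221), HLA-C (-0.99, edgeR adjusted p = 0.155) and B2M (-0.30, edgeR adjusted p = 0.513) did not pass the test. With the replicate block HLA-B (edgeR adjusted p = 0.00205, range over the alternatives 0.00205 to 0.808) and HLA-C (0.00172, range 0.00172 to 0.542) did. Of 8 class II genes, 2 rose, 0 fell and 6 did not pass the test. The class II list gave 4 and 0 adjusted over the list alone, 4 and 1 with the replicate block, and camera adjusted p = 0.00253 (adjusted p = 0.577 with an estimated correlation). They were CD74 and HLA-DMB, a subunit of the peptide exchanger (37.1 ± 11.9 against 5.63 ± 0.700 CPM, log2 fold change 2.72, edgeR adjusted p = 0.00519).

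Genes of interferon signalling showed no common direction in HER2R. The interferon-gamma receptor chain IFNGR2 fell (57.0 ± 9.46 against 103 ± 17.6 CPM, log2 fold change -0.85, edgeR adjusted p = 0.0404). Of 11 alternatives without a left-out library 9 called it, the replicate block among them (edgeR adjusted p = 0.00532). The call ended when any 1 of the 6 libraries was left out. Its log2 fold change stayed at -0.85 without either CEAR library. It ran from -1.03 to -0.66 without an MKN45 or HER2R library, fits that mix line with number. IFNGR1 (-0.49, edgeR adjusted p = 0.125), JAK1 (0.49, edgeR adjusted p = 0.118), JAK2 (-0.33, edgeR adjusted p = 0.402) and IRF1 (-0.34, edgeR adjusted p = 0.441) did not pass. The replicate block called IFNGR1 (edgeR adjusted p = 0.0387, range 0.0387 to 0.389) and JAK1 (0.0189, range 0.0189 to 0.402). Of 24 receptor and JAK-STAT genes, 1 rose, 2 fell and 21 did not pass the test. The JAK-STAT list gave 1 and 2 adjusted over the list alone, 3 and 6 with the replicate block, and camera adjusted p = 0.581. STAT5A rose (1.90, edgeR adjusted p = 0.0182). Of 33 interferon-gamma induced genes, 4 rose, 4 fell and 25 did not pass the test. The interferon-gamma list gave 5 and 5 adjusted over the list alone, 6 and 8 with the replicate block, and camera adjusted p = 0.755. Its median of -0.23 differed in sign from its mean of 0.14. APOL1, an apolipoprotein, rose (3.56, edgeR adjusted p = 0.00502), and WARS, a tRNA synthetase, fell (-1.26, edgeR adjusted p = 0.00491). Of 36 type I interferon stimulated genes, 4 rose, 2 fell and 30 did not pass the test. The type I interferon list gave 5 and 3 adjusted over the list alone, 7 and 10 with the replicate block, and camera adjusted p = 0.978. Here the median was -0.24 and the mean 0.03. BST2, which tethers virions to the cell surface, rose from 4.01 ± 2.39 to 45.7 ± 4.69 CPM (3.49, edgeR adjusted p = 0.00588), and EPSTI1 fell (-1.97, edgeR adjusted p = 0.0221).

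Of 21 checkpoint and immune-suppressive genes, 2 rose, 1 fell and 18 did not pass the test. The checkpoint list gave 3 and 1 adjusted over the list alone, 7 and 1 with the replicate block, and camera adjusted p = 0.0574 (0.0458 with the replicate block, 0.577 with an estimated correlation, range over refits at the preset one 0.0208 to 0.109). NT5E, the ectoenzyme CD73 that makes adenosine, rose from 63.9 ± 2.62 to 119 ± 18.1 CPM (0.90, edgeR adjusted p = 0.0283). The arginase ARG2 rose too (1.64, edgeR adjusted p = 0.0428). CD274, which encodes PD-L1, was scarce, at 0.663 ± 0.433 against 0.153 ± 0.0410 CPM (2.13, edgeR adjusted p = 0.106, 0.0250 with the block, range 0.0250 to 0.452). Of 23 death receptor and extrinsic apoptosis genes, 1 rose, 0 fell and 22 did not pass the test. The death receptor list gave 2 and 4 adjusted over the list alone, 3 and 7 with the replicate block, and camera adjusted p = 0.417. The one called was the TNF receptor TNFRSF1B (0.72, edgeR adjusted p = 0.0333). Of 16 T cell adhesion and NK ligand genes, 1 rose, 0 fell and 15 did not pass the test. The adhesion list gave 1 and 0 adjusted over the list alone, 4 and 2 with the replicate block, and camera adjusted p = 0.213. That gene was ICAM1. Few markers of other cell types passed the filter. The T cell, NK and B cell markers were represented by the kinase LCK alone, which rose (81.3 ± 7.41 against 18.3 ± 8.94 CPM, log2 fold change 2.15, edgeR adjusted p = 0.0215) and carried the list's call (camera adjusted p = 0.0421, adjusted p = 0.577 with an estimated correlation). That list call ended without MKN45 library 2 or either CEAR library (camera adjusted p = 0.0664 without CEAR library 1, 0.0637 without CEAR library 2, 0.0851 without MKN45 library 2). Of 3 measured myeloid markers, 0 rose, 1 fell and 2 did not pass the test. The myeloid list gave 0 and 2 adjusted over the list alone, 0 and 2 with the replicate block, and camera adjusted p = 0.0967 (0.0485 with the replicate block, 0.577 with an estimated correlation, range over refits at the preset one 0.0368 to 0.186). LYZ, a lysozyme that gastric cells also make, fell (-1.42, edgeR adjusted p = 0.0192). Of 2 fibroblast and endothelial markers, 0 rose, 1 fell and 1 did not pass the test. The fibroblast list gave 1 and 1 adjusted over the list alone, 1 and 1 with the replicate block, and camera adjusted p = 0.755. ACTA2 was the one that fell, and the test's direction was down against a list median of 0.21.

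Of 27 NRF2 target and xenobiotic-metabolism genes, 0 rose, 5 fell and 22 did not pass the test. The NRF2 list gave 0 and 6 adjusted over the list alone, 1 and 11 with the replicate block, and camera adjusted p = 0.00329 (adjusted p = 0.577 with an estimated correlation). ALDH1A1, the aldehyde dehydrogenase ALDH3A1 (-2.09, edgeR adjusted p = 0.0127), the glutathione peroxidase GPX2 (-1.17, edgeR adjusted p = 0.0404) and the drug exporter ABCC1 (-0.92, edgeR adjusted p = 0.0208) fell. Of 25 cholesterol synthesis genes, 0 rose, 0 fell and 25 did not pass the test. The cholesterol list gave 0 and 0 adjusted over the list alone, 1 and 13 with the replicate block, and camera adjusted p = 0.0442 (adjusted p = 0.794 with an estimated correlation). That call ended without HER2R library 2 or MKN45 library 1, the latter with the test's direction up. Those fits mix line with number, and 19 of the 25 genes were lower in number 2. Of 22 WNT target genes, 3 rose, 3 fell and 16 did not pass the test. The WNT list gave 7 and 4 adjusted over the list alone, 7 and 4 with the replicate block, and camera adjusted p = 0.213. TNFRSF19 (3.77, edgeR adjusted p = 0.00760) and the WNT inhibitor DKK1 (2.27, edgeR adjusted p = 0.0222) rose, and the transcription factors LEF1 (-4.32, edgeR adjusted p = 0.0258) and ASCL2 (-1.92, edgeR adjusted p = 0.0252) fell. Of 22 receptor tyrosine kinases, 4 rose, 2 fell and 16 did not pass the test. The kinase list gave 6 and 3 adjusted over the list alone, 6 and 4 with the replicate block, and camera adjusted p = 0.597. IGF1R rose (0.67, edgeR adjusted p = 0.0236) and FGFR3 fell (-2.25, edgeR adjusted p = 0.00502). Of 12 measured neighbours of ERBB2 at 17q12, 2 rose, 1 fell and 9 did not pass the test. The neighbour list gave 2 and 1 adjusted over the list alone, 3 and 2 with the replicate block, and camera adjusted p = 0.697. GRB7 (0.96, edgeR adjusted p = 0.0261) and STARD3 (0.85, edgeR adjusted p = 0.0378) rose and PPP1R1B fell (-1.28, edgeR adjusted p = 0.0306). Of 4 cancer-testis and imprinted genes, 1 rose, 2 fell and 1 did not pass the test. The cancer-testis list gave 1 and 3 adjusted over the list alone, and camera adjusted p = 0.426. The growth factor IGF2 rose (4.28, edgeR adjusted p = 0.00758) and MAGEA6 fell (-0.89, edgeR adjusted p = 0.0203), with a list median of -0.85 and a mean of 0.07. Of 18 intestinal differentiation genes, 0 rose, 3 fell and 15 did not pass the test. The intestinal list gave 1 and 5 adjusted over the list alone, 2 and 10 with the replicate block, and camera adjusted p = 0.0574 (3.83e-05 with the replicate block, 0.794 with an estimated correlation, range over refits at the preset one 3.83e-05 to 0.403). HNF4A (-0.85, edgeR adjusted p = 0.0127) and VIL1 (-1.18, edgeR adjusted p = 0.0302) fell. Gastric differentiation genes were called lower with the replicate block (camera adjusted p = 0.0231, 0.153 without it, 0.794 with an estimated correlation, range over refits at the preset one 0.00145 to 0.695). With the replicate block 2419 genes were higher and 2621 lower. The counts fell to 255 and 261 without MKN45 library 1, 196 and 165 without MKN45 library 2, 160 and 54 without HER2R library 1 and 140 and 49 without HER2R library 2. Of the called genes named here for HER2R, EGLN3, AREG, ICAM1, NOG, COL12A1, ARSJ, CD74, CELF2, DOC2B, SLFN11, WNT16, ALDH1A1, SOSTDC1, GAP43, FOXC2, JUN, EREG, NFKB2, HLA-DMB, APOL1, BST2, TNFRSF19 and IGF2 stayed called with any 1 library left out, and the others lost the call with at least 1 of the 6 left out.

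The comparison of CEAR with MKN45 asked the same of cells resistant to the CEACAM5 bispecific. Beside the near loss of CEACAM5, camera at its preset correlation called the MHC class I, interferon, p53, NRF2 and antigen lists lower and the histone and DNA replication lists higher. None of these calls held with an estimated correlation (camera adjusted p = 0.962 for each), a version that again called 0 lists and so does not tell them apart. In each list most members did not pass the test. The histone list, fixed as a check of RNA quality, rose (camera adjusted p = 2.43e-07), so a quality difference stays open. SERPINA1, the protease inhibitor alpha-1-antitrypsin, rose from 0.806 ± 0.339 to 159 ± 57.1 CPM (log2 fold change 7.65, edgeR adjusted p = 0.00241). CLDN18, a claudin of gastric tight junctions, rose from 2.34 ± 0.355 to 38.8 ± 11.3 CPM (4.06, edgeR adjusted p = 0.00241). CDKN1A, the cell-cycle inhibitor p21, fell from 210.5 ± 37.4 to 62.0 ± 8.91 CPM (-1.76, edgeR adjusted p = 0.00639). In all, 385 genes were higher and 541 lower in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 257 and 390 of them by over 2-fold, so that 41.6% of the called genes were higher. Scaling by library size alone gave 51.9%.

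The largest rises included FGL2, a fibrinogen-like immunoregulatory protein (17.7 ± 8.42 against 0.0834 ± 0.0428 CPM, log2 fold change 7.74, edgeR adjusted p = 0.00252), the histone gene HIST1H2BE (76.9 ± 8.46 against 1.18 ± 0.568 CPM, log2 fold change 5.997, edgeR adjusted p = 0.00306), and the metallothionein MT1E (5.58 ± 0.876 against 0.0847 ± 0.0555 CPM, log2 fold change 5.92, edgeR adjusted p = 0.00241). CD74 again rose from 2 counts over both MKN45 libraries, to 24.6 ± 10.9 CPM (1310-fold, 95% counting interval 363 to 10800). Among the largest losses were GNB4, a G protein subunit with 3 counts over both CEAR libraries (16.3 ± 1.39 CPM in MKN45, 448-fold, 95% counting interval 153 to 2170), and TRPS1, a GATA-family repressor with 1 count (8.95 ± 1.98 CPM in MKN45, 746-fold, 95% counting interval 134 to 29500). GAP43 (51.1 ± 22.2 CPM in MKN45), SOSTDC1 (20.5 ± 3.996 CPM) and EDA2R (7.20 ± 0.491 CPM), a receptor of the TNF family, had 0 counts in CEAR, at least 1450-fold, 570-fold and 195-fold lower. Zinc finger genes were among the largest losses. ZNF462 (1930-fold, 95% counting interval 535 to 16000) and ZNF91 (1730-fold, 95% counting interval 310 to 68300) had 2 and 1 counts in CEAR, and ZNF347 had 0, at least 169-fold lower.

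Of 24 MHC class I presentation genes, 0 rose, 4 fell and 20 did not pass the test. The class I list gave 1 and 14 adjusted over the list alone, 1 and 20 with the replicate block, and camera adjusted p = 2.43e-07 (adjusted p = 0.962 with an estimated correlation). TAPBP (134 ± 12.5 against 234 ± 5.40 CPM, log2 fold change -0.81, edgeR adjusted p = 0.0193), TAP1 (-0.95, edgeR adjusted p = 0.0274), TAP2 (-0.59, edgeR adjusted p = 0.0377) and NLRC5 (-1.28, edgeR adjusted p = 0.0264) fell. HLA-B stood at 13.5 ± 5.09 against 76.5 ± 53.9 CPM (-2.50, edgeR adjusted p = 0.0642), HLA-C at 41.2 ± 9.79 against 134 ± 66.4 CPM (-1.70, edgeR adjusted p = 0.0584) and B2M at 236 ± 42.3 against 332 ± 93.0 CPM (-0.49, edgeR adjusted p = 0.341), and none passed the test. With the replicate block all 3 were called lower, at edgeR adjusted p = 0.000122 for HLA-B (range over the alternatives 8.02e-05 to 0.208), 0.000204 for HLA-C (range 0.000204 to 0.193) and 0.0156 for B2M (range 0.0156 to 0.788). Of 8 class II genes, 1 rose, 1 fell and 6 did not pass the test. The class II list gave 1 and 1 adjusted over the list alone, 1 and 2 with the replicate block, and camera adjusted p = 0.920. CD74 rose, and HLA-DMB fell from 5.63 ± 0.700 to 0.311 ± 0.0998 CPM (-4.16, edgeR adjusted p = 0.00608). The median of the class II list was -0.09 and its mean 0.56, and the mean rests on the fitted value of CD74.

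Of 36 type I interferon stimulated genes, 1 rose, 5 fell and 30 did not pass the test. The type I interferon list gave 2 and 14 adjusted over the list alone, 2 and 20 with the replicate block, and camera adjusted p = 1.54e-05 (adjusted p = 0.962 with an estimated correlation). EPSTI1 (1.63 ± 0.0144 against 11.8 ± 2.89 CPM, log2 fold change -2.85, edgeR adjusted p = 0.0115) and the helicase DDX60 (1.79 ± 1.03 against 8.41 ± 0.577 CPM, log2 fold change -2.22, edgeR adjusted p = 0.0251) fell, while BST2 rose (39.6 ± 2.49 against 4.01 ± 2.39 CPM, log2 fold change 3.28, edgeR adjusted p = 0.00883). Of 33 interferon-gamma induced genes, 1 rose, 5 fell and 27 did not pass the test. The interferon-gamma list gave 4 and 10 adjusted over the list alone, 4 and 15 with the replicate block, and camera adjusted p = 0.0252 (adjusted p = 0.962 with an estimated correlation). APOL6 fell (-1.59, edgeR adjusted p = 0.0139) and APOL1 rose (2.01, edgeR adjusted p = 0.0294). That list's call ended without CEAR library 1 or MKN45 library 1, fits that mix line with number. Of 24 interferon receptor and JAK-STAT genes, 1 rose, 1 fell and 22 did not pass the test. The JAK-STAT list gave 3 and 7 adjusted over the list alone, 3 and 8 with the replicate block, and camera adjusted p = 0.464. IFNGR2 fell (44.0 ± 4.32 against 103 ± 17.6 CPM, log2 fold change -1.22, edgeR adjusted p = 0.0190), also with the replicate block (edgeR adjusted p = 0.00126). The call ended without MKN45 library 1 (-1.03), CEAR library 1 (-1.32) or CEAR library 2 (-1.12), fits that mix line with number. STAT5A rose (1.63, edgeR adjusted p = 0.0328). IFNGR1 (0.21, edgeR adjusted p = 0.514), JAK1 (0.17, edgeR adjusted p = 0.606) and JAK2 (0.16, edgeR adjusted p = 0.737) did not pass. Nor did IRF1 (-1.14, edgeR adjusted p = 0.0584), which the replicate block called lower (edgeR adjusted p = 0.00840, range 0.00247 to 0.214).

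Of 21 checkpoint and immune-suppressive genes, 1 rose, 2 fell and 18 did not pass the test. The checkpoint list gave 2 and 3 adjusted over the list alone, 4 and 3 with the replicate block, and camera adjusted p = 0.843. PVRL3, which encodes nectin-3, rose (3.07, edgeR adjusted p = 0.00639). The growth factor TGFB2 (-3.03, edgeR adjusted p = 0.0433) and the B7-family member HHLA2 (-2.15, edgeR adjusted p = 0.0440) fell. CD274 stood at 0.164 ± 0.0410 against 0.153 ± 0.0410 CPM (0.12, edgeR adjusted p = 0.960). Of 23 death receptor and extrinsic apoptosis genes, 0 rose, 2 fell and 21 did not pass the test. The death receptor list gave 0 and 2 adjusted over the list alone, 6 and 4 with the replicate block, and camera adjusted p = 0.555. Those were the caspase inhibitor XIAP (-0.94, edgeR adjusted p = 0.0128) and the TRAIL decoy receptor TNFRSF10C (-1.79, edgeR adjusted p = 0.0394). Of 16 T cell adhesion and NK ligand genes, 1 rose, 2 fell and 13 did not pass the test. The adhesion list gave 3 and 4 adjusted over the list alone, 4 and 4 with the replicate block, and camera adjusted p = 0.920. The costimulatory receptor CD40 rose (3.54, edgeR adjusted p = 0.0115). NCR3LG1, the ligand of an activating NK receptor (-2.10, edgeR adjusted p = 0.0340), and TNFSF9, the ligand of 4-1BB (-3.08, edgeR adjusted p = 0.0335), fell. LCK stood at 18.5 ± 5.68 against 18.3 ± 8.94 CPM (camera adjusted p = 0.941 for the T cell, NK and B cell markers). Of 3 myeloid markers, 0 rose, 0 fell and 3 did not pass the test. The myeloid list gave 0 and 0 adjusted over the list alone, 0 and 1 with the replicate block, and camera adjusted p = 0.843. Of 2 fibroblast and endothelial markers, 0 rose, 0 fell and 2 did not pass the test. The fibroblast list gave 0 and 1 adjusted over the list alone, 0 and 1 with the replicate block, and camera adjusted p = 0.843. Of 10 ERBB receptors and ligands, 1 rose, 0 fell and 9 did not pass the test. The ERBB list gave 2 and 1 adjusted over the list alone, 2 and 2 with the replicate block, and camera adjusted p = 0.920. EREG rose (1.43, edgeR adjusted p = 0.00898), and the test's direction was up against a list median of -0.33 and a mean of -0.24.

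Of 39 replication-dependent histone genes, 3 rose, 0 fell and 36 did not pass the test. The histone list gave 4 and 0 adjusted over the list alone, 21 and 0 with the replicate block, and camera adjusted p = 2.43e-07 (adjusted p = 0.962 with an estimated correlation). HIST1H2BE and HIST1H1D (78.4 ± 4.42 against 21.5 ± 1.15 CPM, log2 fold change 1.86, edgeR adjusted p = 0.0222) were among them. Histone transcripts lack a poly(A) tail, but total RNA libraries need none, so the list does not decide RNA quality. Of 34 DNA replication genes, 2 rose, 0 fell and 32 did not pass the test. The replication list gave 2 and 0 adjusted over the list alone, 9 and 1 with the replicate block, and camera adjusted p = 0.00638 (adjusted p = 0.962 with an estimated correlation). They were the licensing factor CDT1 (0.85, edgeR adjusted p = 0.0223) and GINS2 of the replicative helicase (1.10, edgeR adjusted p = 0.0418). Of 27 p53 targets, 0 rose, 4 fell and 23 did not pass the test. The p53 list gave 0 and 8 adjusted over the list alone, 2 and 12 with the replicate block, and camera adjusted p = 0.00241 (adjusted p = 0.962 with an estimated correlation). CDKN1A, PHLDA3 (-0.95, edgeR adjusted p = 0.0301) and ZMAT3 (-1.01, edgeR adjusted p = 0.0400) were among them. Of 27 NRF2 target genes, 0 rose, 3 fell and 24 did not pass the test. The NRF2 list gave 0 and 4 adjusted over the list alone, 4 and 10 with the replicate block, and camera adjusted p = 0.0252 (adjusted p = 0.962 with an estimated correlation). ALDH1A1 (5.61 ± 3.41 against 118 ± 58.5 CPM, log2 fold change -4.39, edgeR adjusted p = 0.00868), ALDH3A1 (-1.90, edgeR adjusted p = 0.0192) and GPX2 (-1.81, edgeR adjusted p = 0.0159) fell. Without MKN45 library 2, a fit that mixes line with number, the calls of the replication and NRF2 lists ended. The replicate block also called lower the 28 epithelial and junction genes (camera adjusted p = 0.0101, 0.0534 without it, 0.962 with an estimated correlation, range over refits at the preset one 0.00342 to 0.165). It did so for the 25 cholesterol synthesis genes (camera adjusted p = 0.00500, 0.0730 without it, 0.962 with an estimated correlation, range over refits at the preset one 1.84e-14 to 0.650). With the replicate block 1794 genes were higher and 2066 lower, and a fit to these 4 libraries alone gave 170 and 234. The counts were 110 and 231 without MKN45 library 1, 109 and 210 without MKN45 library 2, 164 and 234 without HER2R library 1 and 176 and 252 without HER2R library 2. They were 167 and 116 without CEAR library 1 and 109 and 144 without CEAR library 2. Of those named for CEAR, CEACAM5, SERPINA1, CLDN18, CDKN1A, FGL2, HIST1H2BE, MT1E, CD74, GNB4, TRPS1, GAP43, SOSTDC1, EDA2R, ZNF462, ZNF91, ZNF347, HLA-DMB, BST2, PVRL3, CD40, EREG and ALDH1A1 stayed called with any 1 library left out, and the others lost the call with at least 1 of the 6 left out.

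The derivatives were then compared with each other, which tests the difference between them directly. CEACAM5 was higher in HER2R (log2 fold change 7.51, edgeR adjusted p = 0.0125). By camera at its preset correlation the hypoxia, interferon, NF-kappaB, mesenchymal, MAPK feedback, MHC class II and ribosomal protein lists were called higher in HER2R, and the histone, DNA replication, gastric and GPI anchor lists lower. None of these calls held with an estimated correlation (camera adjusted p = 0.666 to 0.768). Here too that version called 0 lists, so it does not tell them apart. In each list most members did not pass the test. The ribosomal protein list (camera adjusted p = 0.000283) and the histone list (camera adjusted p = 1.71e-08) were fixed as checks of RNA quality. A quality difference stays open. PRKAA2, a catalytic subunit of AMP-activated kinase, was at 57.1 ± 1.49 against 0.463 ± 0.0759 CPM, log2 fold change 6.93, edgeR adjusted p = 0.000192. FUT9, a fucosyltransferase, was at 0.293 ± 0.0178 against 46.9 ± 0.137 CPM, log2 fold change -7.31, edgeR adjusted p = 0.000192. The retinaldehyde dehydrogenase ALDH1A2 stood at 135 ± 28.1 CPM in HER2R and had 0 counts in CEAR, at least 3670-fold higher in HER2R, and TUSC3, a subunit of the oligosaccharyltransferase complex, was at least 560-fold higher. In all, 1095 genes were higher and 1010 lower in HER2R in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 646 and 467 of them by over 2-fold. The 52.0% of called genes that were higher became 41.8% when libraries were scaled by size alone. The CEACAM5 call ended without either HER2R library (edgeR adjusted p = 0.0526 without HER2R library 1, 0.0703 without HER2R library 2). Its log2 fold change moved to 6.83 without HER2R library 2, 6.70 without CEAR library 1 and 9.47 without CEAR library 2.

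Of 36 type I interferon stimulated genes, 8 were higher, 0 lower and 28 did not pass the test. The type I interferon list gave 10 and 0 adjusted over the list alone, 19 and 0 with the replicate block, and camera adjusted p = 0.000171 (adjusted p = 0.729 with an estimated correlation). The antiviral synthetases OAS1 (98.6 ± 26.4 against 32.8 ± 7.92 CPM, log2 fold change 1.59, edgeR adjusted p = 0.0141), OAS2 (1.90, edgeR adjusted p = 0.0171) and OAS3 (1.06, edgeR adjusted p = 0.0275) were among the higher ones. Of 33 interferon-gamma induced genes, 4 were higher, 1 lower and 28 did not pass the test. The interferon-gamma list gave 6 and 2 adjusted over the list alone, 15 and 3 with the replicate block, and camera adjusted p = 0.0471 (adjusted p = 0.761 with an estimated correlation). ICAM1 was higher (12.5 ± 2.30 against 1.51 ± 0.468 CPM, log2 fold change 3.04, edgeR adjusted p = 0.00649). That list's call ended with any of 3 libraries left out (camera adjusted p = 0.193 without CEAR library 1, 0.131 without HER2R library 2, 0.0547 without MKN45 library 2). Of 24 receptor and JAK-STAT genes, 0 were higher, 2 lower and 22 did not pass the test. The JAK-STAT list gave 0 and 0 adjusted over the list alone, 6 and 3 with the replicate block, and camera adjusted p = 0.757. IFNGR1 was lower in HER2R (-0.70, edgeR adjusted p = 0.0449). Of 11 alternatives without a left-out library 9 called it, the replicate block among them (edgeR adjusted p = 0.00805). The call ended when any 1 of the 6 libraries was left out, at log2 fold changes of -0.80 to -0.61. IFNGR2 (0.37, edgeR adjusted p = 0.223), JAK1 (0.31, edgeR adjusted p = 0.257) and JAK2 (-0.49, edgeR adjusted p = 0.203) did not pass. Of 24 MHC class I genes, 2 were higher, 0 lower and 22 did not pass the test. The class I list gave 2 and 0 adjusted over the list alone, 11 and 1 with the replicate block, and camera adjusted p = 0.0760 (0.0167 with the replicate block, 0.879 with an estimated correlation, range over refits at the preset one 0.00160 to 0.564). The peptide trimmers ERAP1 (0.98, edgeR adjusted p = 0.0298) and ERAP2 (1.17, edgeR adjusted p = 0.00942) were those called. HLA-B (1.28, edgeR adjusted p = 0.192), HLA-C (0.72, edgeR adjusted p = 0.259) and B2M (0.19, edgeR adjusted p = 0.675) did not pass. IRF1 (0.80, edgeR adjusted p = 0.0932) and CD274 (2.01, edgeR adjusted p = 0.111) did not pass either. The replicate block called HLA-B (edgeR adjusted p = 0.00156, range 0.00156 to 0.605) and HLA-C (0.00594, range 0.00594 to 0.696) higher. It also called IRF1 (edgeR adjusted p = 0.0269, range 0.0269 to 0.338) and CD274 (0.0274, range 0.0274 to 0.477) higher. Of 8 class II genes, 1 was higher, 0 lower and 7 did not pass the test. The class II list gave 2 and 0 adjusted over the list alone, 3 and 1 with the replicate block, and camera adjusted p = 0.0133 (adjusted p = 0.729 with an estimated correlation). The gene was HLA-DMB (37.1 ± 11.9 against 0.311 ± 0.0998 CPM, log2 fold change 6.87, edgeR adjusted p = 0.00120), and the list call ended without CEAR library 1 (camera adjusted p = 0.0548 without CEAR library 1).

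Of 21 checkpoint and immune-suppressive genes, 3 were higher, 1 lower and 17 did not pass the test. The checkpoint list gave 4 and 2 adjusted over the list alone, 8 and 3 with the replicate block, and camera adjusted p = 0.157. NT5E (1.503, edgeR adjusted p = 0.00751) and TGFB2 (3.91, edgeR adjusted p = 0.0146) were higher and PVRL3 lower (-1.71, edgeR adjusted p = 0.0178) in HER2R. Of 16 T cell adhesion and NK ligand genes, 3 were higher, 2 lower and 11 did not pass the test. The adhesion list gave 5 and 3 adjusted over the list alone, 7 and 3 with the replicate block, and camera adjusted p = 0.157 (0.0347 with the replicate block, 0.729 with an estimated correlation, range over refits at the preset one 0.0347 to 0.161). ICAM1, TNFSF9 (3.26, edgeR adjusted p = 0.0217) and CD70 (2.78, edgeR adjusted p = 0.0309) were higher. Of 23 death receptor and extrinsic apoptosis genes, 1 was higher, 1 lower and 21 did not pass the test. The death receptor list gave 1 and 1 adjusted over the list alone, 5 and 4 with the replicate block, and camera adjusted p = 0.933. XIAP was higher (0.68, edgeR adjusted p = 0.0221) and the kinase RIPK1 lower (-0.82, edgeR adjusted p = 0.0130). LCK was higher (2.14, edgeR adjusted p = 0.0194) and alone made up the T cell, NK and B cell marker list (camera adjusted p = 0.0471, adjusted p = 0.729 with an estimated correlation). Its list call ended without either CEAR library (camera adjusted p = 0.0700 without CEAR library 1, 0.137 without CEAR library 2). Of 3 myeloid markers, 0 were higher, 1 lower and 2 did not pass the test. The myeloid list gave 0 and 1 adjusted over the list alone, and camera adjusted p = 0.228. LYZ was lower (-1.41, edgeR adjusted p = 0.0174). Of 2 fibroblast and endothelial markers, 0 were higher, 0 lower and 2 did not pass the test. The fibroblast list gave 1 and 1 adjusted over the list alone, 1 and 1 with the replicate block, and camera adjusted p = 0.856. Of 6 antigen and CEACAM family genes, 1 was higher, 0 lower and 5 did not pass the test. The antigen list gave 1 and 0 adjusted over the list alone, 2 and 0 with the replicate block, and camera adjusted p = 0.429. ERBB2 did not pass (-0.15, edgeR adjusted p = 0.662). Of 10 ERBB receptors and ligands, 3 were higher, 0 lower and 7 did not pass the test. The ERBB list gave 3 and 1 adjusted over the list alone, 4 and 1 with the replicate block, and camera adjusted p = 0.144. Those were the ligands AREG (2.05, edgeR adjusted p = 0.0173), HBEGF (0.97, edgeR adjusted p = 0.0353) and TGFA (0.84, edgeR adjusted p = 0.0457).

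Of 28 hypoxia and glycolysis genes, 8 were higher, 0 lower and 20 did not pass the test. The hypoxia list gave 11 and 0 adjusted over the list alone, 17 and 1 with the replicate block, and camera adjusted p = 0.000139 (adjusted p = 0.729 with an estimated correlation). The hexokinase HK1 (1.67, edgeR adjusted p = 0.00750) and the glucose transporter SLC2A1 (1.76, edgeR adjusted p = 0.0251) were higher in HER2R. Of 21 NF-kappaB targets, 8 were higher, 0 lower and 13 did not pass the test. The NF-kappaB list gave 10 and 1 adjusted over the list alone, 12 and 3 with the replicate block, and camera adjusted p = 0.00212 (adjusted p = 0.666 with an estimated correlation). The cytokine LIF (1.87, edgeR adjusted p = 0.00942) and the chemokine CXCL1 (3.40, edgeR adjusted p = 0.0122) were higher. Of 19 mesenchymal genes, 8 were higher, 0 lower and 11 did not pass the test. The mesenchymal list gave 9 and 0 adjusted over the list alone, 11 and 1 with the replicate block, and camera adjusted p = 0.000795 (adjusted p = 0.666 with an estimated correlation). VIM (3.25, edgeR adjusted p = 0.0177) and ZEB1 (3.02, edgeR adjusted p = 0.0144) were higher. Of 26 MAPK feedback genes, 5 were higher, 1 lower and 20 did not pass the test. The MAPK list gave 10 and 2 adjusted over the list alone, 13 and 3 with the replicate block, and camera adjusted p = 0.0385 (adjusted p = 0.768 with an estimated correlation). The inhibitor SPRY2 was higher (37.9 ± 2.82 against 8.28 ± 0.556 CPM, log2 fold change 2.20, edgeR adjusted p = 0.0120). The list call ended without CEAR library 2 or HER2R library 2 (camera adjusted p = 0.137 without CEAR library 2, 0.0538 without HER2R library 2). Of 39 ribosomal protein genes, 11 were higher, 0 lower and 28 did not pass the test. The ribosomal protein list gave 20 and 0 adjusted over the list alone, 21 and 2 with the replicate block, and camera adjusted p = 0.000283 (adjusted p = 0.768 with an estimated correlation). RPL27 was one of them (0.94, edgeR adjusted p = 0.0126). This list was a check of RNA quality.

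Of 39 histone genes, 0 were higher, 6 lower and 33 did not pass the test. The histone list gave 0 and 8 adjusted over the list alone, 0 and 34 with the replicate block, and camera adjusted p = 1.71e-08 (adjusted p = 0.729 with an estimated correlation). Of 34 DNA replication genes, 0 were higher, 7 lower and 27 did not pass the test. The replication list gave 1 and 12 adjusted over the list alone, 3 and 15 with the replicate block, and camera adjusted p = 0.00212 (adjusted p = 0.761 with an estimated correlation). CDT1 (-1.26, edgeR adjusted p = 0.00703) and the helicase subunit MCM5 (-0.79, edgeR adjusted p = 0.0240) were lower. Of 21 gastric differentiation genes, 1 was higher, 6 lower and 14 did not pass the test. The gastric list gave 1 and 9 adjusted over the list alone, 3 and 11 with the replicate block, and camera adjusted p = 0.00244 (adjusted p = 0.729 with an estimated correlation). CLDN18 (2.59 ± 0.340 against 38.8 ± 11.3 CPM, log2 fold change -3.91, edgeR adjusted p = 0.00233) and the transcription factor GATA4 (20.2 ± 2.25 against 54.8 ± 0.480 CPM, log2 fold change -1.44, edgeR adjusted p = 0.00699) were lower. SOX2 was higher (25.4 ± 1.28 against 1.25 ± 0.719 CPM, log2 fold change 4.36, edgeR adjusted p = 0.00292). Of 30 GPI anchor genes, 0 were higher, 6 lower and 24 did not pass the test. The GPI anchor list gave 0 and 8 adjusted over the list alone, 0 and 14 with the replicate block, and camera adjusted p = 0.0286 (adjusted p = 0.729 with an estimated correlation). PIGQ (-0.82, edgeR adjusted p = 0.0185) and PGAP1 (-1.21, edgeR adjusted p = 0.0283) were lower. That call ended without CEAR library 2 or HER2R library 1 (camera adjusted p = 0.0734 without CEAR library 2, 0.0560 without HER2R library 1). CEACAM5 is itself held at the membrane by a GPI anchor. Of 4 cancer-testis and imprinted genes, 1 was higher, 1 lower and 2 did not pass the test. The cancer-testis list gave 1 and 2 adjusted over the list alone, 1 and 2 with the replicate block, and camera adjusted p = 0.813. IGF2 was higher (3.09, edgeR adjusted p = 0.0135) and MAGEA6 lower (-0.77, edgeR adjusted p = 0.0259), with a list median of -0.00225 and a mean of 0.58. With the replicate block 2942 genes were higher and 2775 lower. The counts fell to 147 and 46 without HER2R library 1 and 74 and 28 without HER2R library 2. They fell to 239 and 286 without CEAR library 1 and 210 and 150 without CEAR library 2. Of those named between the derivatives, PRKAA2, FUT9, ALDH1A2, TUSC3, HLA-DMB, CLDN18 and SOX2 stayed called with any 1 library left out, and the others lost the call with at least 1 of the 6 left out.

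**Figure D2:**
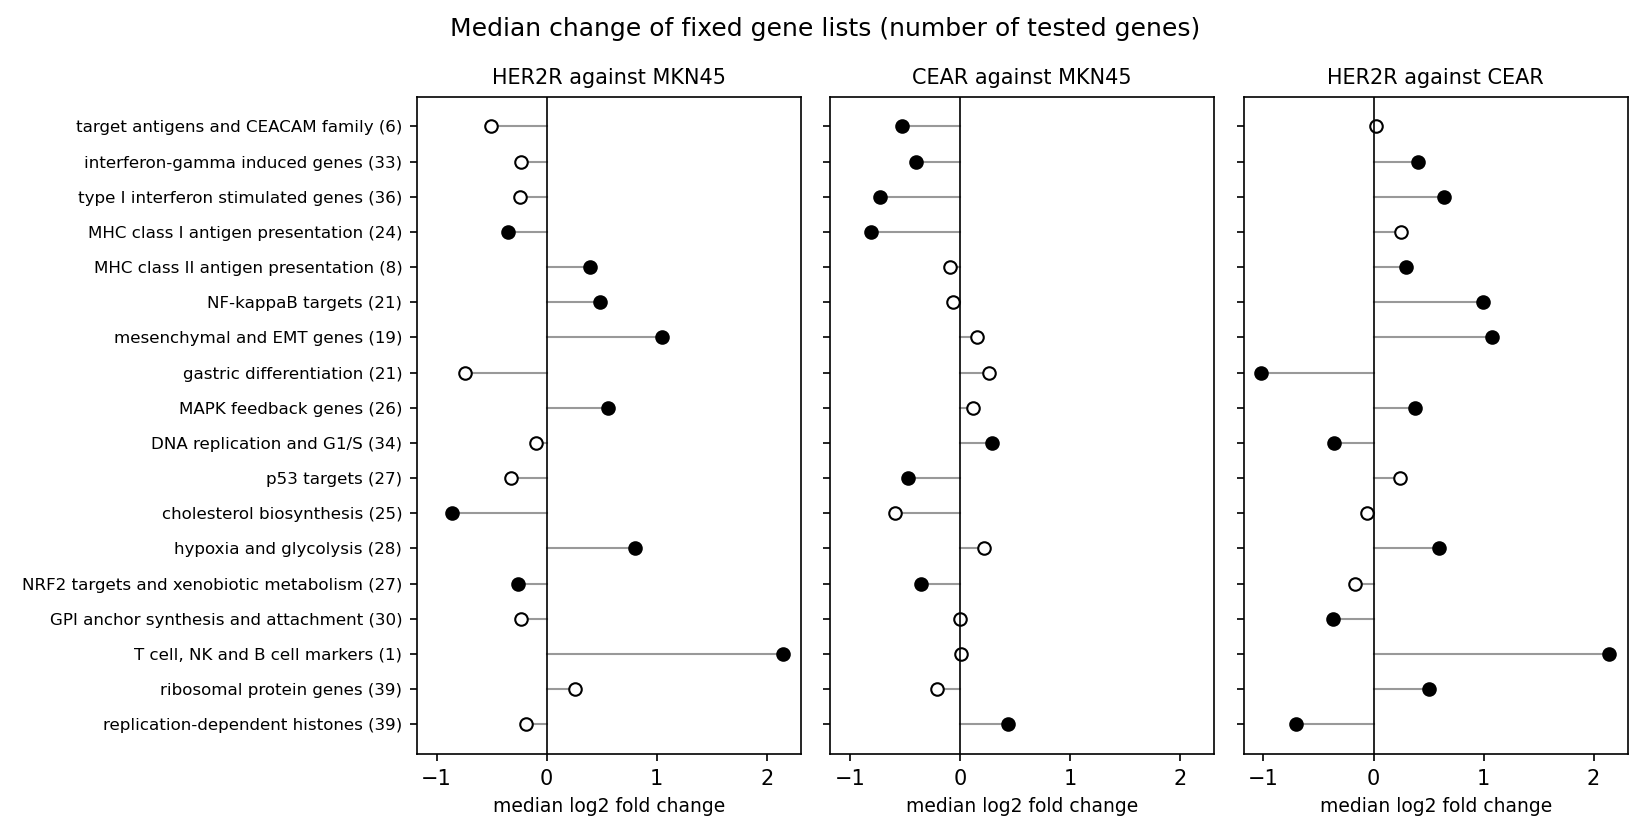
Median log2 fold change of each fixed gene list that camera called in at least 1 comparison, with the number of tested genes in parentheses. Filled points were called with the preset correlation of 0.01 and open points were not; no list was called with an estimated correlation. The ribosomal protein and histone lists were meant as RNA quality checks.

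Finally, the changes of the derivatives against MKN45 were set side by side. Of the genes called in both, 315 changed the same way, 138 higher and 177 lower, and 35 went in opposite directions. Shared rises included CD74, BST2, EREG (15.6 ± 0.9998 CPM in MKN45, 43.1 ± 7.30 in HER2R and 42.0 ± 0.652 in CEAR) and JUN (84.7 ± 0.139, 227 ± 21.4 and 181 ± 18.6 CPM in the same order), and shared losses CEACAM6, GAP43, SOSTDC1, ALDH1A1 and IFNGR2. Independent lists of the same sizes would share 18.8 higher and 26.3 lower genes, and 45.1 in opposite directions. Both comparisons use the same MKN45 libraries, and in 50 simulations of unchanged groups against those libraries at most 1 gene was called the same way. That is chance without any effect, and it does not give the share of the 315 that the common controls add among genes that did change. Over all tested genes, which are not independent replicates, the covariance of the log2 fold changes was 0.352 against a simulated mean of 0.0957, a difference of 0.256, and the correlation was 0.437 against a simulated 0.493. The same sign was seen in 60.3% of genes against a simulated 66.6%. With 2 MKN45 libraries the controls could not be split between the comparisons, so part of the overlap may come from them. With the replicate block 1611 genes changed the same way, and with 1 library left out the count was 124 or 103 (MKN45 library 1 or 2), 69 or 73 (HER2R library 1 or 2) and 128 or 128 (CEAR library 1 or 2).

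**Figure D3:**
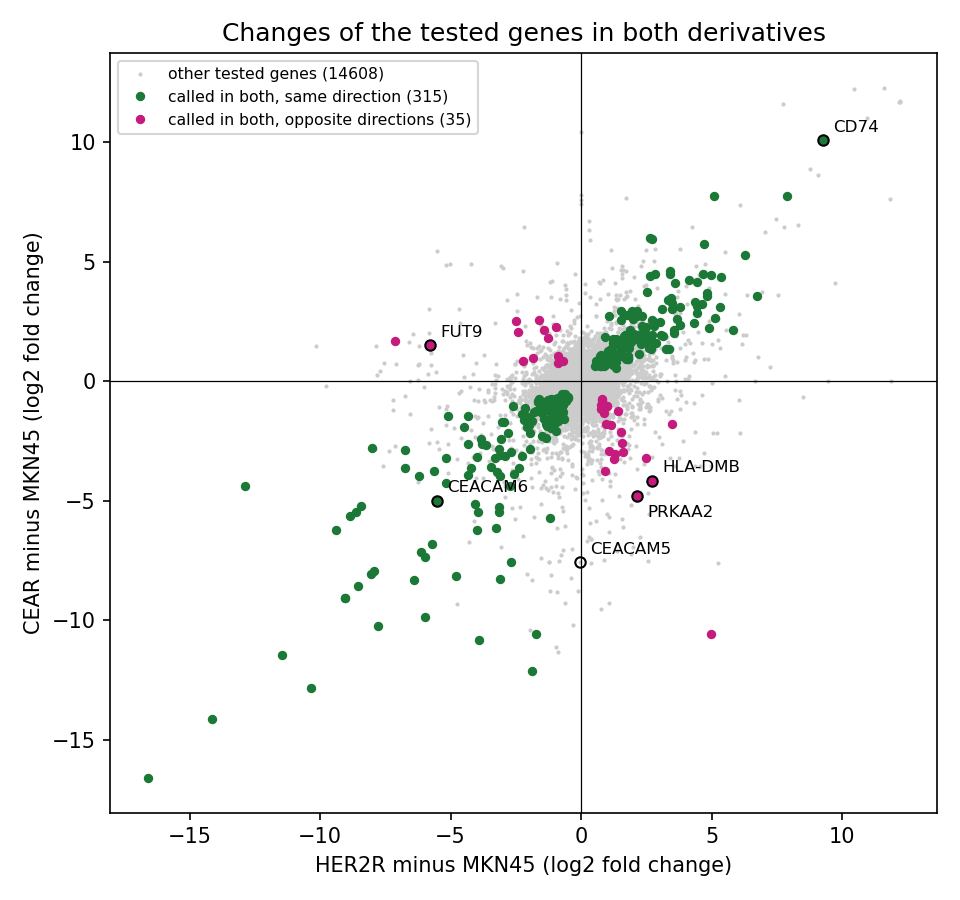
Log2 fold change against MKN45 of each of the 14958 tested genes, HER2R on the x axis and CEAR on the y axis. Green points are the 315 genes called in both in the same direction, pink points the 35 called in opposite directions; values of genes with 3 or fewer counts in a group depend on the prior count and are no bounds.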

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

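The tests here were planned as the comparison of HER2R with CEAR, but the genes were picked after their values were seen. Changes that ran in opposite directions against MKN45 in the derivatives were looked at more closely. There were 35 such genes. As they were picked for opposite calls, a called difference between HER2R and CEAR follows almost by construction and is no further test. Of the 34 with a mean of at least 5 CPM in the highest line, 21 were higher and 13 lower in HER2R. Differences are log2 fold changes of HER2R minus CEAR. FUT9, a fucosyltransferase, stood at 16.4 ± 0.199 CPM in MKN45, 0.293 ± 0.0178 CPM in HER2R and 46.9 ± 0.137 CPM in CEAR, a difference between the derivatives of -7.31 (edgeR adjusted p = 0.000192). PRKAA2, a catalytic subunit of AMP-activated kinase, stood at 13.1 ± 0.989 CPM in MKN45, 57.1 ± 1.49 CPM in HER2R and 0.463 ± 0.0759 CPM in CEAR, a difference between the derivatives of 6.93 (edgeR adjusted p = 0.000192). HLA-DMB, a subunit of the class II peptide exchanger, stood at 5.63 ± 0.700 CPM in MKN45, 37.1 ± 11.9 CPM in HER2R and 0.311 ± 0.0998 CPM in CEAR, a difference between the derivatives of 6.87 (edgeR adjusted p = 0.00120). NRP2, a co-receptor of semaphorins and VEGF, stood at 2.49, 13.8 and 0.271 CPM in MKN45, HER2R and CEAR. Its difference was 5.67 (edgeR adjusted p = 0.00229). FGF2, a fibroblast growth factor, stood at 4.92, 54.2 and 1.41 CPM in MKN45, HER2R and CEAR. Its difference was 5.26 (edgeR adjusted p = 0.00229). SUCNR1, the succinate receptor, stood at 7.46, 1.31 and 43.0 CPM in MKN45, HER2R and CEAR. Its difference was -5.03 (edgeR adjusted p = 0.00551). CEACAM5, whose change differed between the derivatives without opposite calls, showed a difference of 7.51 (edgeR adjusted p = 0.0125). That call ended without either HER2R library.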

How the results depend on the processing

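Values are genes higher and lower, in the order HER2R against MKN45, CEAR against MKN45 and HER2R against CEAR. The replicate block gave 2419 and 2621, 1794 and 2066, and 2942 and 2775, with 1611 genes changed the same way in both derivatives. DESeq2 gave 1361 and 1459, 939 and 1159, and 1783 and 1649, with 741 changed the same way. The test against a fold of 1.5 gave 260 and 147, 126 and 173, and 280 and 155, as its construction requires larger changes. For CEAR against MKN45, the 4 compared libraries alone gave 170 and 234. With 1 library left out the counts ran from 140 to 587 and 49 to 549, from 109 to 176 and 116 to 252, and from 74 to 973 and 28 to 883, and genes changed the same way from 69 to 128, fits with fewer samples. Other counts stayed within 1.5 times the reported ones. Apart from the construction named, the cause was not tested.

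Lists called numbered 9, 8 and 13 in the same order. An estimated correlation left 0, 0 and 0, and fry 1, 0 and 4. The replicate block called 14 in HER2R against MKN45. Leaving out 1 library gave 7 to 16, 9 to 13 and 12 to 14. Under RLE factors or library size alone no called list lost its call or turned. Library size alone also called cholesterol synthesis in CEAR against MKN45 (camera adjusted p = 0.0441, 0.962 with an estimated correlation, range over refits at the preset one 1.84e-14 to 0.650). The cause was not tested.

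ERBB2 in HER2R against MKN45 stayed uncalled, at -0.47 to -0.44 (edgeR, DESeq2 or limma adjusted p = 0.0582 to 0.247), and at -0.59 to -0.31 with 1 library left out (0.141 to 0.495). CEACAM5 in CEAR against MKN45 stayed called, at -7.98 to -7.50 (4.38e-10 to 0.0420), and at -9.52 to -6.76 with 1 library left out (0.0153 to 0.0403). Of 333 called results of named genes, 74 were called in every fit with 1 library left out and 259 were not; 0 reversed in any alternative. The replicate block ended none of the 333 and added 17 of 34 uncalled ones, and no other call of a result in the text changed with it. No filter ended 56, the compared libraries alone 55, limma-voom 30, the legacy method 21, library size alone 11, the 1 CPM filter 8 of 319, DESeq2 3 of 332 and RLE factors 2. Leaving out the 5 noncoding RNAs or thinning, both chosen after seeing the data, ended 2 each. Depth limits folds of genes with 0 to 3 counts in a line to floors or counting intervals. Whether depth or the number of libraries limits other results more was not tested.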

Other observations

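Tests chosen only after the result was seen are those of the number lists, ZNF-named genes, the CEACAM5 neighbours and CEACAM6, carry-over, the thinned count of shared genes, noncoding RNA content and G2/M genes. In a fit over the 3 lines together, 1395 genes were higher and 1098 lower in number 2 than in number 1. Of 30 G2/M genes, which act in mitosis, 0 were higher and 28 lower (camera adjusted p = 9.41e-50, adjusted p = 0.438 with an estimated correlation), CENPE, a mitotic kinesin, among the largest falls (log2 fold change -1.48, edgeR adjusted p = 0.000257). Of 25 cholesterol synthesis genes, 1 was higher and 19 lower (camera adjusted p = 3.91e-17, adjusted p = 0.706 with an estimated correlation), with DHCR7 (-1.59, edgeR adjusted p = 0.00390) and the sterol regulator INSIG1 (-1.92, edgeR adjusted p = 0.00262), and the fatty acid desaturase SCD fell too (-2.15, edgeR adjusted p = 0.00108). Of 39 histone genes, 0 were higher and 21 lower (camera adjusted p = 8.12e-13, adjusted p = 0.706 with an estimated correlation). Of 21 gastric differentiation genes, 10 were higher and 0 lower (camera adjusted p = 4.78e-11, adjusted p = 0.438 with an estimated correlation), TFF1 (3.37, edgeR adjusted p = 0.000346) and MUC5AC (3.04, edgeR adjusted p = 0.00505) among them, and of 18 intestinal ones, 9 and 0 (camera adjusted p = 2.02e-11, adjusted p = 0.706 with an estimated correlation). Of 24 MHC class I genes, 11 were higher and 0 lower (camera adjusted p = 2.07e-05, adjusted p = 0.706 with an estimated correlation), of 27 NRF2 targets 10 and 0 (camera adjusted p = 2.51e-07, adjusted p = 0.438 with an estimated correlation), and of 6 antigen and CEACAM family genes 5 and 0 (camera adjusted p = 3.24e-05, adjusted p = 0.438 with an estimated correlation). Also called were 8 MHC class II genes with 3 and 0 (camera adjusted p = 0.00287, adjusted p = 0.706 with an estimated correlation), 26 MAPK feedback genes with 0 and 4 (camera adjusted p = 0.0283, adjusted p = 0.799 with an estimated correlation), and 28 chromatin silencing genes with 1 and 8 (camera adjusted p = 0.000628, adjusted p = 0.706 with an estimated correlation). The 34 DNA replication genes were not, with 4 and 3 (camera adjusted p = 0.868, median log2 fold change -0.0428).

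Zinc finger genes were frequent among the losses of CEAR. Of 428 tested, 28 were lower and 10 higher than in MKN45, the former against 513 of 14530 other genes (two-sided Fisher's exact p = 0.00232, Benjamini-Hochberg adjusted over 3 comparisons 0.00696). They made up 10 of the 85 genes over 16-fold lower (Fisher's exact p = 0.000153, adjusted 0.000459). Of these 10, 8 lie on chromosome 19, as do 194 of the 421 tested ZNF-named genes with a position (Fisher's exact p = 0.0492, not adjusted). In HER2R 28 were lower and 4 higher (Fisher's exact p for lower = 0.109, adjusted 0.164). They made up 5 of its 61 genes over 16-fold lower (Fisher's exact p = 0.0301, adjusted 0.0451). Between HER2R and CEAR 33 were lower and 31 higher in HER2R (7.71% lower against 6.72% of other genes, Fisher's exact p = 0.433, adjusted 0.433), and no test showed the losses to be particular to CEAR. Genes of a cluster are not independent of one another, which these tests assume.

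The near loss of CEACAM5 in CEAR could come from a lost chromosome segment. The 39 tested protein-coding genes within 1 Mb had a median log2 fold change of 0.0374 (quartiles -0.187 and 0.304), which argues against a segment that reaches most of them. CEACAM6, the next tested gene on one side, was called lower (-4.99, edgeR adjusted p = 0.0487). CEACAM6 fell in HER2R too, which kept CEACAM5, so its fall does not tell whether a short segment with both genes was lost in CEAR, and that stays open, as does loss of CEACAM5 alone. CEACAM5 held 97 and 706 counts in CEAR libraries 1 and 2. MKN45 cells carried over into library 2 would bring 39.7 counts over A1CF, GAP43, SOSTDC1, ZNF462 and ZNF91, and 3 were found (upper 95% limit 8.77), which argues against carry-over as the whole source. Promoter silencing, reads shared with CEACAM relatives and a mixed population stay open as untested.

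The genes changed the same way in both derivatives could reflect chance values of the shared MKN45 libraries. The highest covariance in 50 simulations was 0.104 against 0.352 observed, which argues against this as the whole cause. The correlation (0.437 against a simulated 0.493) and the share of genes with the same sign (60.3% against 66.6%) lay below the simulated means. Changes in only 1 derivative lower both measures, so neither estimates what the controls add. How many of the 315 genes they add stays open. With libraries thinned to equal totals 309 of such genes were called, against 315, which argues against the greater MKN45 depth. A culture or handling difference between MKN45 and both derivatives stays open, as does a common effect of selection, which no test here addressed.

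The differences between numbers 1 and 2 may be technical. With libraries thinned to equal totals the lowest correlation between lines was 0.366, against 0.355 before. Over the 13264 genes with a known exon length it was 0.393, and 0.399 once the trend with length was taken out. The differences did follow length weakly (Spearman correlation -0.101 in MKN45, -0.157 in HER2R and -0.141 in CEAR). These values argue against depth and against length or length-dependent degradation as the whole cause. Noncoding RNA content moved by 3.2 and 2.77 percentage points in MKN45 and CEAR but by -0.96 in HER2R, which argues against it as the common cause. Lower proliferation with more differentiation in number 2 stays open. For it, 28 of 30 G2/M genes were lower in number 2 in all lines, against 25.3% of all tested genes, and 10 of 21 gastric and 9 of 18 intestinal differentiation genes were higher, list calls that were lost with an estimated correlation, as was that of the G2/M list. Against it, the DNA replication genes did not fall as a list. A batch of library preparation cannot be excluded.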
